A study of Mus musculus with 18 samples.

How the data were processed

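Polyadenylated RNA was sequenced from 18 libraries of mouse Th17 cultures, 3 for each of 6 groups formed by 3 genotypes (WT, GLUT3KO and ACLYKO) and by the absence or presence of acetate. Per the labels, 500 ng of total RNA with a RIN above 7.8 went into stranded libraries, which were read as single ends of 75 nt. Bcl2fastq 2.20.0.422, cutadapt, STAR 2.7.2b, featureCounts 1.6.4, DESeq2 and the genome build GRCm38.p6 are named by the authors without stating the role of each or any filter. The deposited table holds TPM, an other unit than counts, as made by the authors, for 45703 genes, with the combined exon length of each gene, also an other unit (bases), given in the deposited table. Each column sums to 1e+06. All 45703 gene IDs matched the RefSeq gene table, and 45701 had the same start and end there.

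TPM times exon length was a whole multiple of 1 step per library in 100% of values under 500 reads, within a tolerance of 0.01 reads, and gave 18.7 to 30.1 M reads per library (median 23.3 M). For a gene with 2000 bases of exons 1 read amounts to 0.0342 to 0.0719 TPM. Genes with a TPM of at least 1 in at least 3 libraries were tested, which left 14229 genes, 11037 of them protein-coding. The table has no protein-coding gene of the mitochondrial chromosome, so that list is not analysed here.

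Group means of log2(TPM + 1) were fitted over all 18 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend and robust on), and p-values were adjusted by Benjamini and Hochberg within each of 11 comparisons, with an adjusted p threshold of 0.05 and no minimum on the change. The comparisons were each loss against WT without and with acetate, acetate in each genotype and averaged over the 3, the differences of the acetate change between each knockout and WT, and GLUT3KO against ACLYKO. The share of WT libraries between both losses was set beside 100 simulations of unchanged groups, and the return of changed genes under acetate beside 100 simulations without an acetate effect. Of 40 gene lists written before the data were examined, the 34 with at least 5 tested members were tested with camera at a correlation of 0.01, again with an estimated correlation, and with fry. B cell, NK and gamma-delta T cell, CD8 T cell, erythroid and neutrophil lists had 4, 4, 2, 1 and 0 tested members and got no list test.

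Replicate numbers are given in the labels without saying what they share. Of all 45 pairs of libraries with the same number, 22 had residuals that correlated by more than 0.1. Among them were all 9 pairs with the same genotype, without and with acetate (0.120 to 0.548). Pairs of different genotypes reached 0.801 (WT and ACLYKO with acetate, both replicate 1), and those of untreated WT and ACLYKO had 0.285 to 0.577. Those of untreated WT and GLUT3KO had 0.721, 0.622 and -0.354 for replicates 1, 2 and 3. Of the 18 libraries 13 correlated best with those of their own number, so the number may mark something shared across genotypes. This was looked at before the calls were compared, and the acetate comparisons were therefore also fitted with a block for genotype and number, whose value is printed where it changes a call that the text gives for a gene, or a count of genes by more than 1.5 times. Both losses without acetate were also fitted with a block for number alone, in which 0 of the genes named by the rule below lost their call. Named genes followed a rule fixed before the data were examined: the targeted genes, 11 fixed genes (among them Il17a, Il17f, Il21, Il22, Csf2, Ifng, Il2, Slc2a1, Acss1 and Acss2) in the 5 comparisons of a loss or of acetate in 1 genotype, up to 4 members with the smallest adjusted p of each list discussed, and the 10 largest rises and 10 largest falls (5 and 5 for the acetate average and the interactions). The last part took genes past the threshold whose 3 and 3 libraries did not overlap and whose higher mean was at least 5 TPM, without unnamed gene models, pseudogenes and antigen receptor segments. The rule takes more genes than the text names, and those not reported here stay in the counts and list tests. Genes outside this rule, Foxp3, Lyz2, Csf1r, C1qa, Itgam, H2-Aa, Ifnb1 and the cytokines named for the comparisons between genotypes with acetate were chosen after their values were seen.

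Alternatives were another pseudocount, no filter and a stricter one, median-ratio scaling, quantile normalization, a fit of only the groups compared, arrayWeights, robust off, a minimum log2 change of 1, replicate blocks and leaving out each library in turn. Voom on the recovered reads, a correction of each library for GC content and length, the score on the main axis of variation within groups as a covariate, and leaving out the 5 libraries with a score above 0 were added after seeing the data. That axis held 63.6% of the variance within groups, and its loadings correlated across genes with GC content (Spearman rho = -0.478) and exon length (0.350). The test was tested on simulated data with 200 changed genes, where at most 9.46% of calls were false in any comparison. The simulated noise was independent between genes and libraries, with 1 spread per gene in all groups. It does not hold the main axis, so the share of false calls in the real libraries may differ. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.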

Results

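Messenger RNA was sequenced from 18 cultures of mouse Th17 cells, the helper T cells that make interleukin-17, grown from naive CD4+ T cells in polarizing medium. The cells were wild type (WT), lacked the glucose transporter GLUT3 (gene Slc2a3, here GLUT3KO) or lacked ATP citrate lyase (gene Acly, here ACLYKO). This enzyme makes cytosolic acetyl-CoA from citrate. Each genotype was cultured without or with acetate, another source of acetyl-CoA, for the 24 hours that followed 48 hours of polarization. All cells were then restimulated for 5 hours with PMA and ionomycin in the presence of secretion blockers. The labels give the acetate dose as 20 mM in the sample protocols and as 10 mM in the series text. There were 6 groups of 3 libraries. Depth was 18.7 to 30.1 M gene-assigned reads per library (median 23.3 M). Levels below are the mean ± SD of 3 libraries in TPM, and log2 changes are on the log2(TPM + 1) scale with their standard error, which understates changes of low genes. Nothing in the labels says whether the 3 libraries of a group came from separate mice, so p-values measure the spread between these samples, which may be technical.

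The targeted genes were read first. Acly (GeneID 104112, chromosome 11, 100476352 to 100528000, GRCm38.p6) stood at 396 ± 4.27 TPM in WT and at 11.3 ± 3.85 TPM in ACLYKO without acetate, and at 11.9 ± 0.913 TPM in ACLYKO with acetate. Every ACLYKO library lay below every library of the other genotypes. In GLUT3KO, Acly was higher than in WT, at 679 ± 65.8 TPM (log2 change 0.77 ± 0.22, limma adjusted p = 0.0128). Slc2a3 (GeneID 20527, chromosome 6, 122727809 to 122802363) fell from 17.7 ± 2.91 TPM in WT to 6.17 ± 2.10 TPM in GLUT3KO (log2 change -1.41 ± 0.28, limma adjusted p = 0.00118). With acetate it was 31.02 ± 1.53 TPM in WT and 10.6 ± 2.64 TPM in GLUT3KO. Slc2a3 was 10.2 ± 3.91 TPM in ACLYKO without acetate, where replicate 1 (5.76 TPM) lay within the range of the GLUT3KO libraries. The values are per gene, so reads over the deleted exons were not separated from the rest.

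**Figure D1:**
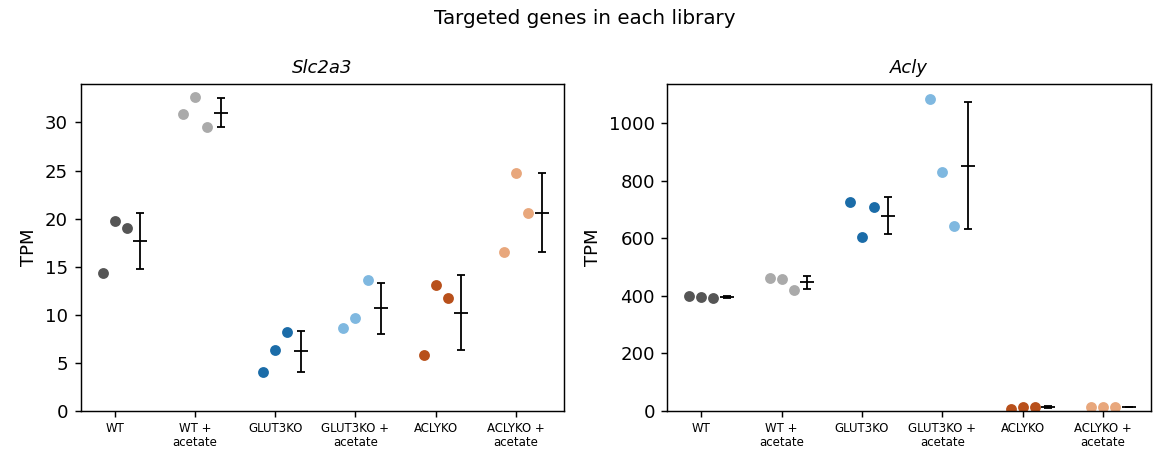
TPM of Slc2a3 (left) and Acly (right) on a linear axis in each of the 18 libraries by group, with points for libraries and a black mark for the mean with its SD. Acly lies between 7.01 and 14.4 TPM in the 6 ACLYKO libraries and at 392 TPM or more in the other 12.

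GLUT3 loss was examined by comparing untreated GLUT3KO with untreated WT cells. The hallmark cytokine genes of Th17 cells were lower: Il17a fell from 638 ± 56.3 to 145 ± 50.8 TPM. Il17f fell from 762 ± 99.1 to 105 ± 0.688 TPM (log2 changes of both genes -2.19 ± 0.39 and -2.84 ± 0.22). Il2, the T cell growth factor, fell from 5412 ± 1233 to 434 ± 96.3 TPM and Csf2, which encodes GM-CSF, from 343 ± 77.1 to 118 ± 35.8 TPM. In contrast Ifng, the signature cytokine gene of Th1 cells, rose from 44.2 ± 13.4 to 877 ± 297 TPM (log2 change 4.26 ± 0.37, limma adjusted p = 6.36e-07). Il21 and Il22 rose by 1.19 and 2.46 on the log2 scale. Slc2a1, which encodes the glucose transporter GLUT1, was 80.2 ± 3.51 TPM in WT and 114 ± 5.99 TPM in GLUT3KO (limma adjusted p = 0.172). It passed in 4 alternatives, such as a fit of these 6 libraries alone (0.0268). It did not pass in the other 4 comparisons of a loss or of acetate in 1 genotype (0.283 to 0.990), but did so in some alternatives: without ACLYKO replicate 1 it was higher under ACLY loss (log2 change 0.77) and lower with acetate in ACLYKO (-0.64, adjusted p at most 3.92e-04 in both).

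Genes with the largest rises under GLUT3 loss included the adjacent type IV collagen genes Col4a2 and Col4a1, from 0.503 ± 0.251 to 83.2 ± 29.9 TPM and from 0.577 ± 0.307 to 71.2 ± 25.3 TPM. Their annotated ends overlap on opposite strands, and the strand setting of the read counting is not given in the sources used here. Spp1, which encodes the secreted protein osteopontin, rose from 6.07 ± 0.462 to 319.9 ± 55.3 TPM. Map2k6, a kinase upstream of p38, rose from 2.39 ± 0.373 to 85.3 ± 12.4 TPM. Trpm6, Foxq1, Dpysl3 and Dsp rose by 4.67, 4.52, 4.47 and 4.46 on the log2 scale. Besides the cytokines, the largest falls were in Cd5l (-3.39), the chemokine genes Cxcl3 (-3.33) and Cxcl2 (-3.17), Lad1 (-2.71), Stra6 (-2.42) and Trat1 (-2.38).

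Among the gene lists, Th1 and cytotoxic genes had 11 of 14 tested members higher and 1 lower, and 12 changed adjusted over the list alone (median log2 change 2.10, camera adjusted p = 2.38e-04, adjusted p = 0.499 with an estimated correlation). The perforin gene Prf1 rose from 1.44 ± 0.369 to 20.9 ± 8.66 TPM, Gzmc from 8.32 ± 3.33 to 91.4 ± 43.0 TPM and the IL-18 receptor gene Il18r1 from 1.71 ± 0.391 to 15.8 ± 4.05 TPM. The TGF-beta targets had 7 of 9 tested members higher and 0 lower, and 7 changed adjusted over the list alone (median log2 change 0.93, camera adjusted p = 0.00320, adjusted p = 0.202 with an estimated correlation). Tgfbr1 was at 127 ± 9.92 against 30.2 ± 2.75 TPM and Smad3 at 48.8 ± 3.22 against 13.3 ± 2.48 TPM. The unfolded protein response had 8 of 18 tested members higher and 0 lower, and 11 changed adjusted over the list alone (median log2 change 0.60, camera adjusted p = 0.0131, adjusted p = 0.724 with an estimated correlation), led by the chaperone gene Dnajb9 (log2 change 1.80 ± 0.16).

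Among the other lists called under GLUT3 loss, MYC targets and ribosome biogenesis had 0 of 25 tested members higher and 12 lower, and 15 changed adjusted over the list alone (median log2 change -0.71, camera adjusted p = 6.65e-08, adjusted p = 0.202 with an estimated correlation). The pentose phosphate pathway had 1 of 9 tested members higher and 3 lower, and 7 changed adjusted over the list alone (median log2 change -0.43, camera adjusted p = 0.0131, adjusted p = 0.724 with an estimated correlation). Nuclear-encoded oxidative phosphorylation had 0 of 50 tested members higher and 4 lower, and 0 changed adjusted over the list alone (median log2 change -0.36, camera adjusted p = 6.24e-05, adjusted p = 0.733 with an estimated correlation). Rrp9 and Nop56, both of ribosome biogenesis, had log2 changes of -1.41 and -1.04. Oxidative phosphorylation lost its call after correction for GC content and length. NRF2 targets of oxidative stress had 8 of 14 tested members higher and 0 lower, and 8 changed adjusted over the list alone (median log2 change 0.77, camera adjusted p = 0.0421, adjusted p = 0.301 with an estimated correlation). Srxn1 was at 61.0 ± 9.40 against 4.56 ± 0.583 TPM. Regulatory T cell genes had 7 of 14 tested members higher and 1 lower, and 8 changed adjusted over the list alone (median log2 change 0.52, camera adjusted p = 0.0299, adjusted p = 0.499 with an estimated correlation). Nt5e, which encodes CD73, was at 311 ± 38.3 against 19.8 ± 3.99 TPM and the receptor gene Gpr83 at 46.6 ± 8.60 against 7.08 ± 2.25 TPM. Foxp3, the lineage factor gene of these cells, was at 1.33 ± 0.128 against 0.744 ± 0.109 TPM (limma adjusted p = 0.136). Both of these lists lost their call under several alternatives, and with an estimated correlation no list kept one.

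In all, 4753 of 14229 tested genes differed between untreated GLUT3KO and WT (limma, adjusted p under 0.05), 3548 higher and 1205 lower, of which 1948 changed by at least 1 on the log2 scale. The share of higher genes was 74.6% with TPM and 54.1% with median-ratio scaling, 51.8% with quantile normalization and 46.7% with the GC and length correction. Median-ratio scaling moved the median change of all genes from 0.17 to -0.02, so the excess of higher genes rests on the scaling, and with the GC and length correction it turned. Leaving out 5 libraries that stood apart within their groups (WT replicate 1, GLUT3KO replicates 1 and 3, ACLYKO replicate 1 and ACLYKO with acetate replicate 1) gave 7578 genes, with 1 GLUT3KO library left that is assumed to vary like the other groups.

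**Figure D2:**
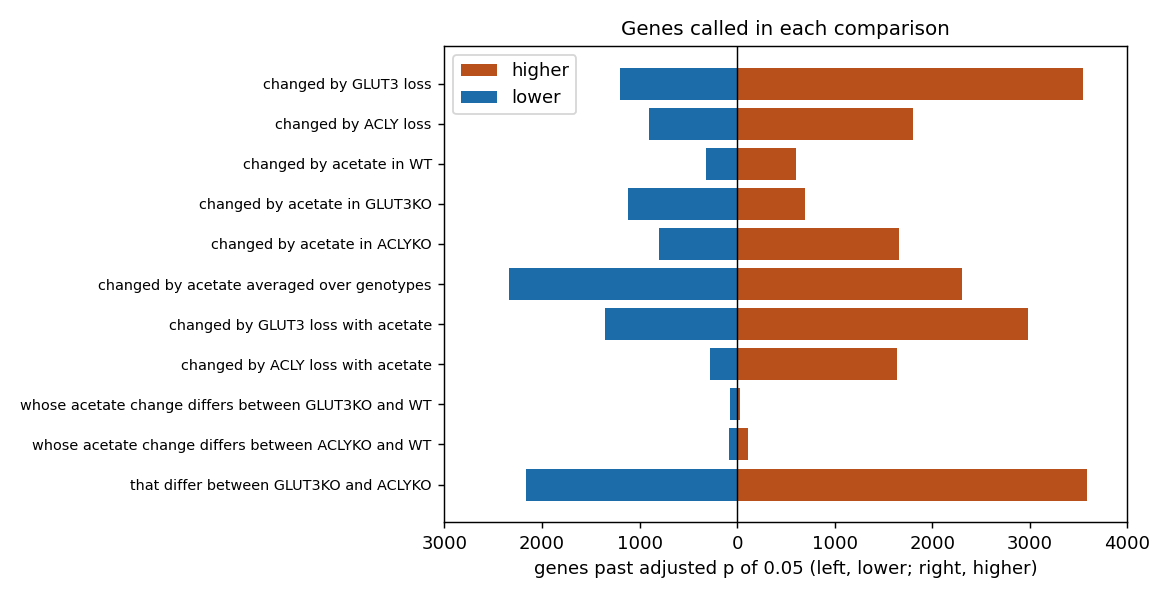
Number of genes past a limma adjusted p of 0.05 in each of the 11 comparisons, on a linear axis, with higher genes to the right and lower genes to the left. The difference between GLUT3KO and ACLYKO has the most calls (5746) and the difference of the acetate change between GLUT3KO and WT the fewest (110).

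ACLY loss was examined by comparing untreated ACLYKO with untreated WT cells. Il17a fell from 638 ± 56.3 to 104 ± 60.0 TPM and Il17f from 762 ± 99.1 to 289.8 ± 120.4 TPM (log2 changes -2.83 ± 0.39 and -1.46 ± 0.22). Csf2 fell from 343 ± 77.1 to 154 ± 31.7 TPM. Il2 rose from 5412 ± 1233 to 13290.0 ± 5778 TPM, opposite to its change under GLUT3 loss, and Ifng rose from 44.2 ± 13.4 to 155 ± 58.3 TPM. Il9, the signature gene of Th9 cells, had the largest rise, from 1.68 ± 0.712 to 132 ± 42.6 TPM (log2 change 5.62 ± 0.25, limma adjusted p = 8.66e-09). Il21 was 1171 ± 471 TPM in WT and 1044 ± 99.2 TPM in ACLYKO (limma adjusted p = 0.780). Acss2, whose product makes acetyl-CoA from acetate, rose from 2.81 ± 0.475 to 6.52 ± 1.72 TPM.

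Type I interferon response genes were the list that stood out most, with 17 of 20 tested members higher and 0 lower, and 18 changed adjusted over the list alone (median log2 change 1.72, camera adjusted p = 1.52e-16, adjusted p = 8.99e-04 with an estimated correlation). Irf7, a transcription factor of the response, was at 15.8 ± 5.73 TPM in ACLYKO and 0.0617 ± 0.0135 TPM in WT. Ifit1 was at 4.29 ± 0.676 against 0.139 ± 0.0738 TPM, Zbp1 at 32.8 ± 1.03 against 4.43 ± 0.563 TPM and Isg15 at 103 ± 69.6 against 3.48 ± 1.35 TPM. Ifi211, Mndal and Ifi203 were also among the largest rises (4.08, 3.28 and 3.27 on the log2 scale), but these belong to a family of close paralogs whose reads the counting could split. Without ACLYKO replicate 1, 17 of the 20 list members were called higher, 16 of them also with all libraries.

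Cell cycle genes were higher as well. The S phase list had 19 of 24 tested members higher and 0 lower, and 19 changed adjusted over the list alone (median log2 change 0.96, camera adjusted p = 1.09e-09, adjusted p = 0.610 with an estimated correlation). Tyms was at 14.2 ± 0.127 against 4.20 ± 0.998 TPM and Cdc6 at 29.8 ± 3.19 against 8.52 ± 2.47 TPM. The G2 and M phase list had 10 of 24 tested members higher and 0 lower, and 16 changed adjusted over the list alone (median log2 change 1.36, camera adjusted p = 3.24e-05, adjusted p = 0.722 with an estimated correlation). Genes of cholesterol synthesis and uptake had 8 of 23 tested members higher and 1 lower, and 10 changed adjusted over the list alone (median log2 change 0.34, camera adjusted p = 0.00333, adjusted p = 0.680 with an estimated correlation). Among them Cyp51 and Stard4 rose by 0.92 and 1.13 on the log2 scale. LXR targets, which respond to sterols, had 1 of 6 tested members higher and 4 lower, and 5 changed adjusted over the list alone (median log2 change -0.71, camera adjusted p = 0.0273, adjusted p = 0.610 with an estimated correlation). Abca1 and Abcg1, which encode cholesterol exporters, had log2 changes of -0.98 and -0.71. In all 6 alternatives ended the call of this list, among them leaving out ACLYKO replicate 3 or the 5 libraries that stood apart (named with the counts). T cell identity genes had 0 of 16 tested members higher and 3 lower, and 3 changed adjusted over the list alone (median log2 change -0.46, camera adjusted p = 0.00423, adjusted p = 0.345 with an estimated correlation). The costimulatory receptor gene Cd28 was at 401 ± 51.6 against 898 ± 71.3 TPM.

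After Acly itself the largest falls under ACLY loss were in Upp1, which encodes uridine phosphorylase, from 71.0 ± 4.92 to 2.68 ± 1.53 TPM, and in Serpinf1, from 57.4 ± 9.62 to 2.27 ± 0.895 TPM. Plin2, which encodes a coat protein of lipid droplets, fell from 18.8 ± 3.998 to 1.48 ± 0.739 TPM. Aldoc, a glycolytic aldolase gene, fell from 24.3 ± 0.568 to 2.78 ± 1.38 TPM and Cxcl3 from 102 ± 6.10 to 9.16 ± 4.36 TPM. The MHC class II chain gene H2-Ab1 fell from 34.8 ± 3.76 to 3.08 ± 0.838 TPM while Cd74, which encodes the invariant chain, rose from 33.7 ± 3.77 to 421 ± 194 TPM. The mitochondrial tRNA genes TrnG, TrnH and TrnT also ranked among the largest rises, and all 3 lost their call without ACLYKO replicate 1 (adjusted p 0.056 to 0.074), as they did without WT replicate 2 or 3 (0.056 to 0.091).

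In all, 2715 genes differed between untreated ACLYKO and WT, 1807 higher and 908 lower. Higher genes were 66.6% of them, 52.6% with median-ratio scaling and 49.2% with the GC and length correction, so this excess depends on the setting too. A fit of only these 6 libraries called 342 genes, and Il17a, Il17f, Csf2, Ifng and Il2 were not among them (limma adjusted p = 0.056, 0.088, 0.09, 0.078 and 0.18 in that fit), while leaving out WT replicate 2 or 3 called 1795 or 1778 and leaving out the 5 libraries that stood apart 7068.

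**Figure D3:**
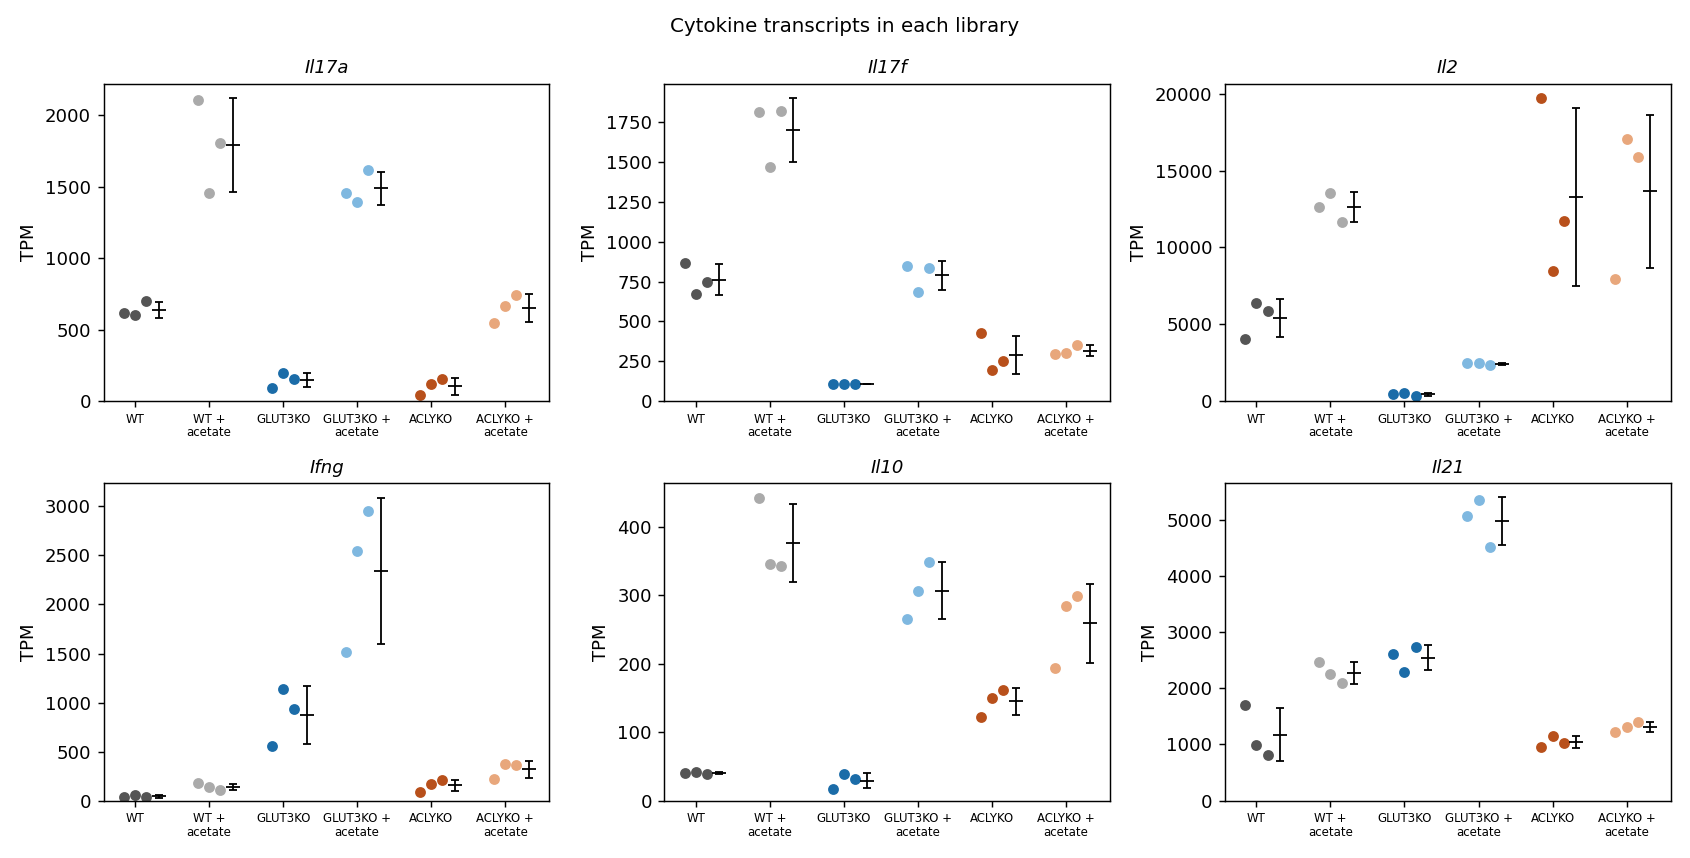
TPM of 6 cytokine genes on linear axes in each of the 18 libraries by group, with points for libraries and a black mark for the mean with its SD. Il17a is lower in both untreated knockouts than in WT and higher with acetate in each genotype, while Il2 is lowest in untreated GLUT3KO.

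Acetate in WT cells was followed by higher cytokine transcripts. Il10, which encodes an anti-inflammatory cytokine, had the largest rise, from 40.7 ± 1.54 to 377 ± 56.9 TPM (log2 change 3.17 ± 0.25, limma adjusted p = 1.15e-05). Il17f rose from 762 ± 99.1 to 1701 ± 203 TPM, Il21 from 1171 ± 471 to 2274 ± 189 TPM. Il22 rose from 1.08 ± 0.727 to 8.39 ± 2.204 TPM. Il17a was 638 ± 56.3 TPM without and 1792 ± 327 TPM with acetate (log2 change 1.48 ± 0.39, limma adjusted p = 0.0355). The Il17a call ended when any 1 of the 6 libraries was left out (adjusted p 0.071 to 0.14) and with no filter on low values (0.059). Il2 passed (limma adjusted p = 0.0297) and did not with the replicate block by genotype (adjusted p = 0.096) or when any 1 library but WT replicate 2 was left out (0.06 to 0.14). Csf2 did not pass (343 ± 77.1 and 436 ± 80.3 TPM). The list of T cell cytokines and chemokines had 18 of 27 tested members higher and 0 lower, and 20 changed adjusted over the list alone (median log2 change 1.16, camera adjusted p = 2.85e-18, adjusted p = 0.0362 with an estimated correlation). Tnf was at 1489 ± 138 against 488 ± 32.5 TPM and Lta at 469.9 ± 33.0 against 143 ± 16.5 TPM.

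Th17 lineage genes had 8 of 19 tested members higher and 0 lower, and 11 changed adjusted over the list alone (median log2 change 0.35, camera adjusted p = 7.10e-07, adjusted p = 0.0362 with an estimated correlation) with acetate in WT. Ahr, Il1r1 and Il23r rose by 1.47, 1.27 and 0.97 on the log2 scale. Th1 and cytotoxic genes had 5 of 14 tested members higher and 0 lower, and 8 changed adjusted over the list alone (median log2 change 0.81, camera adjusted p = 1.92e-06, adjusted p = 0.200 with an estimated correlation). Tbx21, which encodes the Th1 factor T-bet, was at 19.2 ± 2.73 against 4.30 ± 0.401 TPM. The follicular helper and exhaustion list had 1 of 10 tested members higher and 0 lower, and 3 changed adjusted over the list alone (median log2 change 0.61, camera adjusted p = 9.73e-04, adjusted p = 0.200 with an estimated correlation). Its 1 called member was the chemokine receptor gene Cxcr5, at 9.45 ± 0.802 against 1.76 ± 0.229 TPM. The unfolded protein response had 0 of 18 tested members higher and 3 lower, and 3 changed adjusted over the list alone (median log2 change -0.43, camera adjusted p = 2.42e-05, adjusted p = 0.203 with an estimated correlation), the opposite direction to GLUT3 loss. Sel1l was at 65.4 ± 3.26 against 126 ± 39.4 TPM. TGF-beta targets had 1 of 9 tested members higher and 0 lower, and 1 changed adjusted over the list alone (median log2 change 0.33, camera adjusted p = 0.00679, adjusted p = 0.150 with an estimated correlation). Lists called with no member past the threshold were glycolysis (median log2 change 0.29), histone acetyltransferases (-0.39) and G2 and M phase (-0.59), with adjusted p = 0.666, 0.666 and 0.685 with an estimated correlation. Each lost its call when WT replicate 1 (the last 2) or WT replicate 2 or 3 (glycolysis) was left out.

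Other large rises with acetate in WT were Clec2i (2.56), Il24 (2.43), Pdlim4 (2.27), Rcn3 (2.27), the tetraspanin gene Cd63 (2.15) and the small GTPase gene Rhoc (2.09). The largest falls were in the trypsinogen genes Try5, from 27.0 ± 3.72 to 3.02 ± 0.881 TPM, and Try4, from 14.7 ± 5.77 to 1.34 ± 0.148 TPM, paralogs between which reads could be split. Cox6a2, Tmtc2 and Mxd4 had log2 changes of -2.15, -1.98 and -1.58. Altogether 925 genes differed, 601 higher and 324 lower. Higher genes made up 64.97% of them, 55.2% with the GC and length correction, 52.0% without the 5 libraries that stood apart, 51.6% with arrayWeights and 46.2% with the axis score as a covariate. Leaving out 1 library called 451 to 641. A fit of these 6 libraries alone called 1462, and leaving out the 5 libraries that stood apart called 3889.

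In GLUT3KO cells acetate was followed by higher Il17a, from 145 ± 50.8 to 1488 ± 115 TPM, and Il17f, from 105 ± 0.688 to 789 ± 91.4 TPM (log2 changes 3.41 ± 0.39 and 2.89 ± 0.22, limma adjusted p = 6.75e-05 and 2.49e-06). Il2 rose from 434 ± 96.3 to 2409 ± 53.3 TPM and Csf2 from 118 ± 35.8 to 346 ± 24.6 TPM. Il22 rose from 10.9 ± 5.86 to 48.0 ± 11.6 TPM. Il10 rose from 28.9 ± 11.0 to 307 ± 41.6 TPM. Ifng was 877 ± 297 TPM without and 2339 ± 742 TPM with acetate (limma adjusted p = 0.0197). It lost its call without GLUT3KO replicate 1 or without GLUT3KO with acetate replicate 2 or 3 (adjusted p 0.078 to 0.1). The cytokine list had 22 of 27 tested members higher and 0 lower, and 25 changed adjusted over the list alone (median log2 change 1.51, camera adjusted p = 9.85e-24, adjusted p = 0.0273 with an estimated correlation). Immediate early and TCR response genes had 5 of 23 tested members higher and 0 lower, and 7 changed adjusted over the list alone (median log2 change 0.39, camera adjusted p = 9.52e-05, adjusted p = 0.320 with an estimated correlation). Nr4a1 was at 24.8 ± 4.47 against 8.99 ± 0.946 TPM. Th1 and cytotoxic genes had 3 of 14 tested members higher and 0 lower, and 7 changed adjusted over the list alone (median log2 change 0.60, camera adjusted p = 9.52e-05, adjusted p = 0.371 with an estimated correlation). The chemokine receptor gene Cxcr3 was at 26.3 ± 2.91 against 4.01 ± 1.81 TPM.

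The largest falls with acetate in GLUT3KO were in Try4, from 52.4 ± 6.41 to 1.88 ± 0.170 TPM, and Try5, from 84.9 ± 26.7 to 4.17 ± 0.362 TPM. Pls1, Dgkk, P2ry1, Papss2 and the activating receptor gene Cd226 had log2 changes of -3.01, -2.62, -2.45, -2.35 and -2.38. Pdlim4, Ccn1, Rhoc and Il4 rose by 3.41, 3.10, 2.77 and 2.56. NRF2 targets had 0 of 14 tested members higher and 3 lower, and 4 changed adjusted over the list alone (median log2 change -0.39, camera adjusted p = 0.0264, adjusted p = 0.271 with an estimated correlation). Nqo1 was at 4.03 ± 0.316 against 19.8 ± 5.37 TPM. HIF targets outside glycolysis had 3 of 17 tested members higher and 1 lower, and 6 changed adjusted over the list alone (median log2 change 0.45, camera adjusted p = 0.0264, adjusted p = 0.271 with an estimated correlation). Histone acetyltransferases had 0 of 14 tested members higher and 2 lower, and 9 changed adjusted over the list alone (median log2 change -0.58, camera adjusted p = 0.0247, adjusted p = 0.777 with an estimated correlation). Regulatory T cell genes had 3 of 14 tested members higher and 0 lower, and 4 changed adjusted over the list alone (median log2 change 0.16, camera adjusted p = 0.0264, adjusted p = 0.443 with an estimated correlation). Oxidative phosphorylation (median log2 change 0.31, 1 of 50 members called) and the G2 and M phase list (median -0.84, 0 of 24 called) were called with adjusted p = 0.823 in both with an estimated correlation. The calls of these last 6 lists each ended under 3 or more alternatives, and the direction of oxidative phosphorylation turned without the 5 libraries that stood apart (camera adjusted p = 0.408). In all, 1813 genes differed, 691 higher and 1122 lower. Of these 38.1% were higher with TPM and 58.8% with median-ratio scaling, and 50.6% with the GC and length correction. Leaving out 1 library other than GLUT3KO replicate 2 called 960 to 1130 genes.

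In ACLYKO cells acetate was followed by higher Il17a, from 104 ± 60.0 to 649.9 ± 100.3 TPM (log2 change 2.85 ± 0.39, limma adjusted p = 1.34e-04). Il17f (289.8 ± 120.4 and 315 ± 33.8 TPM), Il2 (13290.0 ± 5778 and 13639 ± 4959 TPM), Il21, Il22, Csf2 and Ifng did not pass the test (limma adjusted p = 0.583, 0.934, 0.314, 0.285, 0.254 and 0.0574). Ifng passed with the replicate block by genotype (adjusted p = 0.011), and Il17f passed without ACLYKO replicate 1 (log2 change 0.51, adjusted p = 0.031). Acss1, a mitochondrial acetyl-CoA synthetase gene, rose from 0.569 ± 0.0234 to 2.47 ± 0.0793 TPM. Th17 lineage genes had 12 of 19 tested members higher and 1 lower, and 13 changed adjusted over the list alone (median log2 change 0.79, camera adjusted p = 1.79e-05, adjusted p = 0.0531 with an estimated correlation). The chemokine receptor gene Ccr6 was at 122 ± 11.9 against 21.3 ± 4.99 TPM.

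The type I interferon list fell with acetate in ACLYKO, with 0 of 20 tested members higher and 11 lower, and 12 changed adjusted over the list alone (median log2 change -1.004, camera adjusted p = 4.20e-11, adjusted p = 0.00559 with an estimated correlation). Irf7 fell from 15.8 ± 5.73 to 1.05 ± 0.483 TPM, Ifit1 from 4.29 ± 0.676 to 0.193 ± 0.0526 TPM and Ifi44 from 5.38 ± 1.34 to 0.147 ± 0.127 TPM. Cytokines and chemokines had 12 of 27 tested members higher and 2 lower, and 15 changed adjusted over the list alone (median log2 change 0.57, camera adjusted p = 0.00298, adjusted p = 0.608 with an estimated correlation). Th1 and cytotoxic genes had 8 of 14 tested members higher and 0 lower, and 8 changed adjusted over the list alone (median log2 change 1.13, camera adjusted p = 4.49e-05, adjusted p = 0.255 with an estimated correlation). Follicular helper and exhaustion genes had 6 of 10 tested members higher and 0 lower, and 7 changed adjusted over the list alone (median log2 change 0.91, camera adjusted p = 0.00298, adjusted p = 0.219 with an estimated correlation). Tbx21 was at 23.5 ± 2.55 against 2.85 ± 1.09 TPM and Cxcr5 at 13.4 ± 1.55 against 0.510 ± 0.299 TPM. Regulatory T cell genes had 6 of 14 tested members higher and 0 lower, and 10 changed adjusted over the list alone (median log2 change 0.62, camera adjusted p = 8.37e-04, adjusted p = 0.219 with an estimated correlation). T cell identity genes had 7 of 16 tested members higher and 0 lower, and 8 changed adjusted over the list alone (median log2 change 0.68, camera adjusted p = 0.00983, adjusted p = 0.219 with an estimated correlation). Glycolysis had 5 of 21 tested members higher and 0 lower, and 6 changed adjusted over the list alone (median log2 change 0.53, camera adjusted p = 0.0238, adjusted p = 0.679 with an estimated correlation), and lost its call without ACLYKO replicate 1.

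Plin2 rose with acetate in ACLYKO from 1.48 ± 0.739 to 17.4 ± 0.734 TPM and Rhoc from 4.26 ± 1.72 to 39.2 ± 6.14 TPM. Tff1, Lgals7, Rcn3, Tgm2 and Pdlim4 rose by 4.47, 3.21, 3.04, 3.03 and 2.99 on the log2 scale. Try4, Try5, the growth factor gene Areg and the chemokine gene Cxcl10 had log2 changes of -3.47, -3.53, -2.50 and -2.09. In all, 2458 genes differed, 1661 higher and 797 lower. With quantile normalization 1438 were higher and 1369 lower. Higher genes were 67.58% of those called, and this turned to 46.1% with arrayWeights and 44.6% without the 5 libraries that stood apart. A fit of these 6 libraries alone called 424 genes, and Il17a was not among them (adjusted p = 0.055).

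**Figure D4:**
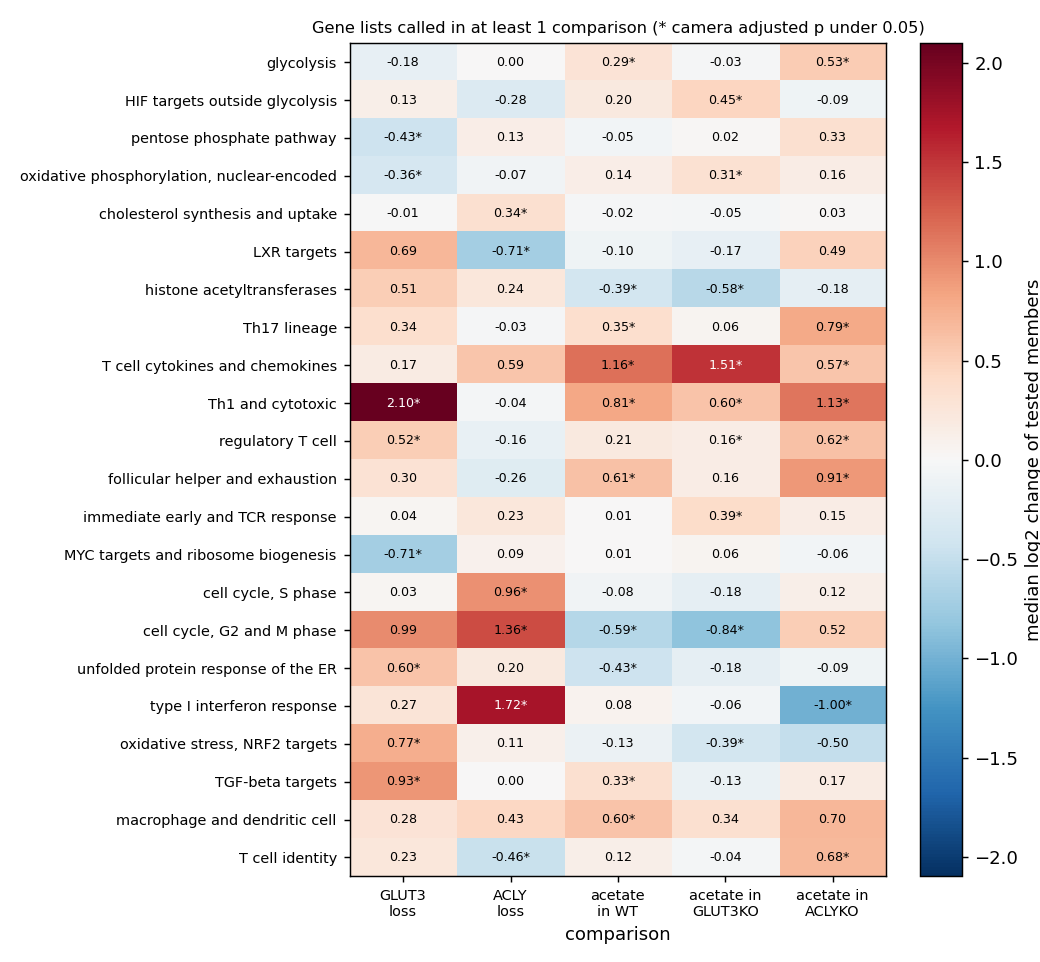
Median log2 change of the tested members of each gene list (rows) in 5 comparisons (columns), as color and number, for lists called in at least 1 of them, with a star where the camera adjusted p is under 0.05. Cytokines and chemokines are starred in all 3 acetate columns, and the interferon list is 1.72 under ACLY loss.

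Averaged over the 3 genotypes, 4648 genes differed with acetate, 2306 higher and 2342 lower. Which were more depended on the setting (44.5% higher with quantile normalization, 53.8% with median-ratio scaling). Across genes the average change correlated with the loadings of the main axis within groups (Spearman rho = -0.594) and with GC content (0.318). Of the 5 libraries with a score above 0 on that axis, all but ACLYKO with acetate replicate 1 were untreated. Acetate and the axis are thus partly aligned, and some of these differences may follow the axis. Il17a and Il10 rose by 2.58 ± 0.23 and 2.47 ± 0.14 on the log2 scale (limma adjusted p = 1.33e-06 and 4.17e-08), with Pdlim4 (2.89), Tff1 (2.76) and Rhoc (2.62). Try4 and Try5 both had a log2 change of -3.45, and Cox6a2, Neto2 and P2ry1 had log2 changes of -2.46, -1.50 and -1.50.

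Whether acetate acted differently in the knockouts was tested by interaction terms. The acetate change differed between GLUT3KO and WT in 110 genes, or 32 with a replicate block by genotype and number, 30 of them shared. Leaving out any 1 of the 12 libraries compared but WT replicate 1 or GLUT3KO replicate 2 called 40 to 70, and the other alternatives gave 21 (pseudocount of 0.1) to 6418 (arrayWeights). Among those called, Il17f had a larger rise in GLUT3KO (difference 1.73 ± 0.32, limma adjusted p = 0.0176, and 0.07 with the replicate block). This call also ended without WT with acetate replicate 2 or 3, GLUT3KO replicate 3 or GLUT3KO with acetate replicate 1 or 3 (0.052 to 0.067). The difference for Il17a was 1.94 ± 0.55 (limma adjusted p = 0.178). Il1a, Ccn1 and Mylk2 differed by 3.05, 2.30 and 2.07, and Angptl2, Dgkk and Cd226 by -3.10, -2.46 and -2.06. Between ACLYKO and WT, 191 genes differed in their acetate change, or 100 with the replicate block, 88 of them shared. Leaving out any 1 WT library, without or with acetate, or ACLYKO with acetate replicate 2 or 3, called 93 to 126, and leaving out ACLYKO replicate 1 called 386. The other alternatives gave 56 (only the groups compared) to 1831 (arrayWeights). The interferon list led, with 0 of 20 tested members higher and 10 lower, and 13 changed adjusted over the list alone (median log2 change -1.16, camera adjusted p = 1.16e-23, adjusted p = 1.51e-04 with an estimated correlation). Irf7 differed by -3.21 ± 0.31 and Ifi44 by -2.44 ± 0.19. The counts of both interactions were matched by 8 and 7 of 100 splits of the genotype labels, the real one included. Il9 differed by -2.52, and Serpinf1, H2-Ab1 and Tgm2 by 2.41, 2.15 and 2.18 (Tgm2 did not pass with the replicate block, adjusted p = 0.078).

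In the presence of acetate, 4329 genes differed between GLUT3KO and WT (2977 higher, 1352 lower). Il17a was 1488 ± 115 TPM against 1792 ± 327 TPM in WT with acetate (limma adjusted p = 0.676). Il17f was lower (789 ± 91.4 against 1701 ± 203 TPM, adjusted p = 0.00147) and Ifng higher (2339 ± 742 against 142 ± 31.9 TPM). The unfolded protein response had 14 of 18 tested members higher and 0 lower, and 16 changed adjusted over the list alone (median log2 change 0.93, camera adjusted p = 5.05e-06, adjusted p = 0.358 with an estimated correlation). MYC targets had 0 of 25 tested members higher and 11 lower, and 13 changed adjusted over the list alone (median log2 change -0.64, camera adjusted p = 5.05e-06, adjusted p = 0.358 with an estimated correlation). Those higher were 68.8% with TPM and 50.4% with quantile normalization, and 47.8% with the GC and length correction.

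With acetate, 1925 genes differed between ACLYKO and WT (1643 higher, 282 lower), among them Il17a, at 649.9 ± 100.3 against 1792 ± 327 TPM. The G2 and M phase list had 24 of 24 tested members higher and 0 lower, and 24 changed adjusted over the list alone (median log2 change 2.39, camera adjusted p = 1.99e-15, adjusted p = 0.270 with an estimated correlation). The S phase list had 19 of 24 tested members higher and 0 lower, and 21 changed adjusted over the list alone (median log2 change 1.09, camera adjusted p = 1.46e-11, adjusted p = 0.266 with an estimated correlation). p53 targets had 0 of 20 tested members higher and 6 lower, and 11 changed adjusted over the list alone (median log2 change -0.50, camera adjusted p = 1.53e-07, adjusted p = 0.0491 with an estimated correlation). The share of higher genes was 85.4% with TPM and 58.6% with quantile normalization. Without WT with acetate replicate 1 or 2 or ACLYKO with acetate replicate 1, 1120 to 1273 genes were called. Without acetate, GLUT3KO and ACLYKO differed from each other in 5746 genes. S phase genes were lower in GLUT3KO, with 0 of 24 tested members higher and 17 lower, and 17 changed adjusted over the list alone (median log2 change -1.20, camera adjusted p = 3.22e-08, adjusted p = 0.276 with an estimated correlation). The share of genes higher in GLUT3KO was 62.3% with TPM and 49.4% with quantile normalization, and 48.4% with the GC and length correction.

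The changes under both losses were compared with each other. Across the tested genes, which are not independent replicates, the log2 changes under GLUT3 loss and ACLY loss correlated with r = 0.23, and 711 genes were higher and 156 lower under both, against 451 and 76.9 for independent lists. Another 418 were called in opposite directions, against 379 for independent lists. Il17a, Il17f, Csf2 and Cxcl3 were lower in both knockouts, and Il2 changed in opposite directions. Under ACLY loss Il17a, Il17f, Csf2 and Il2 did not pass in the fit of only the 6 libraries compared. Both comparisons share the WT libraries. In 100 simulations of unchanged groups the correlation had a median of 0.57 (-0.85 to 0.98), and at most 45 genes were higher and 64 lower in both and 0 called in opposite directions. Few genes are called in unchanged groups, so these counts cannot show how much sharing adds to lists with real changes. The observed covariance was 0.116, the simulated median 0.0313 and the simulated range -0.133 to 0.527. The 3 WT libraries were not split between both comparisons, and part of the excess may come from sharing them. For pairs of comparisons with no shared library, the correlation was 0.24 between GLUT3 loss without acetate and ACLY loss with acetate, and 0.082 for the reverse. Leaving out WT replicate 1 moved the first correlation to 0.40 and leaving out ACLYKO replicate 1 moved it to 0.098.

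Genes changed by a loss were then followed under acetate in the same knockout. The 908 genes lower in ACLYKO had a median log2 acetate change of 0.63 in ACLYKO and 0.047 in WT, above the 0.0288 (-0.189 to 0.527) of 100 simulations with no acetate effect. Of these genes 440 were called higher with acetate, such as Il17a, Plin2 and Serpinf1, and 10 lower. The median of these lower genes lay within that simulated range under 7 alternatives, so its place above the range depends on the setting. It was 0.42 without ACLYKO replicate 1, 0.32 without the 5 libraries that stood apart, 0.44 with median-ratio scaling, 0.42 with quantile normalization, 0.32 with the GC and length correction, 0.36 with arrayWeights and 0.37 with the axis score as a covariate. The range was simulated for the TPM values alone. It took the observed means of the untreated groups, with their noise, as true, which may understate a return by chance alone. The 1807 genes higher in ACLYKO had a median of -0.26, within the simulated range (-0.424 to 0.144), with 466 called lower, such as Irf7 and Ifit1, and 113 higher. In GLUT3KO, the 1205 lower genes had a median acetate change of 0.17 (simulated 0.052, range -0.219 to 0.68) and the 3548 higher genes one of -0.25 (simulated -0.023, range -0.291 to 0.133), both within the simulated range. With acetate on both sides, 70.2% of the genes lower in GLUT3KO and 20.4% of those lower in ACLYKO were still called lower than in WT. The difference between both shares was not tested, and the second depends on the setting. With median-ratio scaling the shares were 64.2% and 28.8%, with quantile normalization 72.3% and 30.4%, with the GC and length correction 72.9% and 32.7%, and with arrayWeights 71.3% and 60.3%. A fit of only the groups compared gave 94.4% and 76.6% (of 94 genes), and leaving out the 5 libraries that stood apart 91.7% and 42.3%. The second share was 37.2% without ACLYKO replicate 1.

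Lists of other cell types served as a check of what the cultures held. Of 17 macrophage and dendritic cell genes 6 were tested, and the list was called with acetate in WT (median log2 change 0.60, camera adjusted p = 0.0149, adjusted p = 0.451 with an estimated correlation), with 1 called member, H2-Eb1. The list's call ended without the 5 libraries that stood apart. The fibroblast and endothelial list was not called in the 5 comparisons of the gene list plot (camera adjusted p 0.0803 to 0.754), but was lower in ACLYKO than in WT with acetate (median -0.44, camera adjusted p = 0.00241, adjusted p = 0.0573 with an estimated correlation). Lyz2, Csf1r and C1qa, abundant in macrophages, were at most 0.081 TPM in the untreated ACLYKO libraries.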

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

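The tests of the 3 patterns below were chosen after the results were seen, except the GC and length test of the ACLYKO library. The splits of the libraries were planned, except those that keep the pairs and the division by imbalance.

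ACLYKO replicate 1 stood apart from the other 2 libraries of its group, with a lowest correlation of 0.874 where the other pairs within groups had at least 0.957. After the correction for GC content and length it was 0.899 against 0.963, which argues against these trends as the whole cause, although they may be part of it. Acly stood at 7.01 TPM in this library and at 392 TPM or more in the 12 libraries of other genotypes, which argues against a library of another genotype. It had 21.5 M reads, and 4 libraries with fewer reads had no correlation under 0.9 within their group, which argues against depth as the whole cause. Of these 4, WT replicate 1 and GLUT3KO replicate 3 are among the 5 libraries with an axis score above 0, and GLUT3KO with acetate replicate 3 and ACLYKO with acetate replicate 3 are not. No biological explanation was tested, and RNA quality or a separate culture stays open.

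The higher type I interferon genes in untreated ACLYKO did not rest on that library, since 17 of 20 tested members were called higher without it (camera adjusted p = 6.73e-16), and 18 of 20 after the GC and length correction. RNA from other cells would bring their abundant genes, and the smallest rise among the members called higher was 1.001 TPM. The highest rise was 0.0302 TPM among Lyz2, Csf1r, C1qa and Itgam, which argues against RNA from macrophages. RNA from dendritic or other antigen-presenting cells stays open, since Cd74 rose by 387 TPM, H2-Ab1 fell and H2-Aa was 0.244 TPM in WT and 0.647 TPM in ACLYKO. Cd74 was added to these genes after its rise was seen. No biological explanation was tested, and a difference between cultures that moves with the genotype stays open.

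The higher cytokine genes with acetate kept a camera adjusted p of at most 0.00013 in each genotype after the GC and length correction, and of at most 2.54e-05 without the 5 libraries with an axis score above 0, which argues against both as the whole cause. With an estimated correlation the list was called in WT and GLUT3KO (adjusted p = 0.0362 and 0.0273) and not in ACLYKO (0.608). A stronger response to the final restimulation cannot be told apart from an effect of acetate on cytokine genes. The list of immediate early and TCR response genes was called higher in 1 of 3 genotypes (GLUT3KO, median log2 change 0.39, camera adjusted p = 9.52e-05). In WT its median was 0.00658 (camera adjusted p = 0.163), and in ACLYKO it was 0.149 with 2 members called higher and 5 lower (camera adjusted p = 0.525). These 2 rows do not support a stronger response in WT and ACLYKO, but a p that misses the threshold and members that go both ways do not exclude it. The list was read only at the end of the 5 hours of restimulation, so an earlier difference in these genes could have been missed. All cultures were restimulated before they were collected.

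The acetate change differed by an interaction test between GLUT3KO and WT in 110 genes. Higher in GLUT3KO were Il1a (3.05), Il23a (2.87), Ccn1 (2.30), Gstt1 (2.22), Mylk2 (2.07) and Il17f (1.73), and lower were Angptl2 (-3.10), Dgkk (-2.46), Ifi209 (-2.26), Ephx1 (-2.26) and Cd226 (-2.06), as differences of log2 changes. Between ACLYKO and WT it differed in 191 genes, with Serpinf1 (2.41), H1f0 (2.32), Tgm2 (2.18), H2-Ab1 (2.15) and Cxcl3 (2.12) higher and Irf7 (-3.21), Il9 (-2.52), Isg20 (-2.49), Ifi44 (-2.44) and Snord4a (-2.41) lower in ACLYKO. With the replicate block by genotype Il17f, Ifi209 and Ephx1 did not pass for GLUT3KO (adjusted p = 0.07, 0.063 and 0.066), nor did Tgm2, Isg20 and Snord4a for ACLYKO (0.078, 0.062 and 0.066).

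By the planned splits, chance was not excluded for either interaction. Of 100 splits of the genotype labels within each acetate state, 8 called at least 110 genes for GLUT3KO (highest other 1585) and 7 at least 191 for ACLYKO (highest other 3928). Splits that call many times the real count point to a structure of the libraries: all 7 and 6 of these other splits had a genotype imbalance of 2 or more between the acetate states, which moves the genotype difference into the interaction. The 91 other splits with less imbalance, a division made after this was seen, called at most 14 and 122 genes. In 10 splits that keep the pairs, added after this was seen, the highest other counts were 2 and 1, and 10 splits are too few for a share under 0.05. For acetate averaged over genotypes 1 of 100 splits, the real one, called as many as 4648 genes (highest other 3323, and 2358 among splits that part all pairs). This share is under 0.05, which argues against chance but does not exclude it, since some wrong splits also called many genes.

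The comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05, and in each 1 split, the real one, called as many genes. The real and the highest other counts were 4753 and 813 for GLUT3 loss, 2715 and 0 for ACLY loss, 925 and 1 for acetate in WT, 1813 and 1 for acetate in GLUT3KO, 2458 and 0 for acetate in ACLYKO, 4329 and 1 for GLUT3 loss with acetate, 1925 and 0 for ACLY loss with acetate, and 5746 and 3457 for GLUT3KO against ACLYKO. The splits with 813 and 3457 put GLUT3KO replicates 1 and 3 with WT replicate 1 and with ACLYKO replicate 1, libraries with an axis score above 0. For ACLY loss and acetate in each genotype, the other splits that part all pairs of libraries with the same number called 0 genes.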

How the results depend on the processing

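The alternatives were fixed before the data were examined, except voom on the recovered reads, the correction for GC content and length, the axis score as a covariate and the fit without the 5 libraries with an axis score above 0, which were chosen after seeing the data. The planned DESeq2 fit was not run, because the table holds TPM, and the recovered reads were fitted with voom only. A count below was changed by more than 1.5 times, and its cause was not tested. The minimum on the log2 change by construction asks for more, and left-out libraries leave fewer samples. Fewer samples do not explain the counts that rose when libraries were left out. The main axis was taken from the variation within groups of these same libraries. Its score as a covariate, or leaving out the 5 libraries chosen by it, takes away spread that the axis was built to hold. Higher counts in these settings are therefore no independent evidence that more genes changed.

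With limma arrayWeights (gene by gene, since its REML method did not converge), the count was 10631 for GLUT3 loss, 6899 for ACLY loss, 4728 for acetate in WT, 9713 for acetate in GLUT3KO, 6470 for acetate in ACLYKO, 9686 for the acetate average, 9997 for GLUT3 loss with acetate, 7843 for ACLY loss with acetate, 6418 for the GLUT3KO interaction, 1831 for the ACLYKO interaction and 9906 for GLUT3KO against ACLYKO. With an added minimum of 1 on the absolute log2 change, the count was 1948 for GLUT3 loss, 1112 for ACLY loss, 273 for acetate in WT, 541 for acetate in GLUT3KO, 987 for acetate in ACLYKO, 453 for the acetate average, 1703 for GLUT3 loss with acetate, 692 for ACLY loss with acetate, 69 for the GLUT3KO interaction and 2718 for GLUT3KO against ACLYKO. With the axis score as a covariate, the count was 7671 for GLUT3 loss, 4889 for ACLY loss, 2990 for acetate in WT, 3841 for acetate in GLUT3KO, 4325 for acetate in ACLYKO, 7550 for GLUT3 loss with acetate, 4554 for ACLY loss with acetate, 462 for the GLUT3KO interaction, 966 for the ACLYKO interaction and 8840 for GLUT3KO against ACLYKO. With the 5 libraries with an axis score above 0 left out, the count was 7578 for GLUT3 loss, 7068 for ACLY loss, 3889 for acetate in WT, 3496 for acetate in GLUT3KO, 5783 for acetate in ACLYKO, 7230 for the acetate average, 9350 for GLUT3 loss with acetate, 5376 for ACLY loss with acetate, 454 for the GLUT3KO interaction and 1022 for the ACLYKO interaction. With only the groups compared in the fit, the count was 342 for ACLY loss, 1462 for acetate in WT, 424 for acetate in ACLYKO, 9393 for GLUT3 loss with acetate, 3459 for ACLY loss with acetate, 192 for the GLUT3KO interaction, 56 for the ACLYKO interaction and 2440 for GLUT3KO against ACLYKO. With GC and length correction, the count was 1605 for acetate in WT and 294 for the ACLYKO interaction. With a pseudocount of 0.1, the count was 21 for the GLUT3KO interaction. With no filter on low values, the count was 171 for the GLUT3KO interaction. With a filter of TPM of at least 5 in at least 3 samples, the count was 55 for the GLUT3KO interaction and 94 for the ACLYKO interaction. With quantile normalization, the count was 66 for the GLUT3KO interaction. With the replicate block by genotype, the count was 32 for the GLUT3KO interaction and 100 for the ACLYKO interaction. With voom on the recovered reads, the count was 33 for the GLUT3KO interaction and 116 for the ACLYKO interaction.

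With estimated correlation the number of lists was 0 for GLUT3 loss, 1 for ACLY loss, 2 for acetate in WT, 1 for acetate in GLUT3KO and 1 for acetate in ACLYKO. With fry the number of lists was 20 for GLUT3 loss, 13 for ACLY loss and 15 for acetate in ACLYKO. With no filter on low values the number of lists was 10 for ACLY loss. With quantile normalization the number of lists was 5 for acetate in GLUT3KO and 13 for acetate in ACLYKO. With limma arrayWeights (gene by gene, since its REML method did not converge) the number of lists was 5 for acetate in GLUT3KO and 13 for acetate in ACLYKO. The median acetate changes of genes lowered or raised by a loss moved by more than their spread as follows. For genes lowered in ACLYKO (0.63) it was 0.83 with a pseudocount of 0.1, 0.56 with no filter on low values, 0.70 with a filter of TPM of at least 5 in at least 3 samples, 0.44 with median-ratio scaling, 0.42 with quantile normalization, 0.90 with only the groups compared in the fit, 0.36 with limma arrayWeights, 0.82 with voom on the recovered reads, 0.32 with GC and length correction, 0.37 with the axis score as a covariate and 0.32 with the 5 libraries with an axis score above 0 left out. For genes raised in GLUT3KO (-0.25) it was -0.20 with no filter on low values, -0.12 with median-ratio scaling, -0.19 with quantile normalization, -0.36 with limma arrayWeights, -0.27 with the replicate block by number, -0.19 with voom on the recovered reads, -0.14 with GC and length correction, -0.21 with the axis score as a covariate and -0.18 with the 5 libraries with an axis score above 0 left out. For genes lowered in GLUT3KO (0.17) it was 0.25 with median-ratio scaling, 0.37 with limma arrayWeights, 0.23 with the replicate block by number, 0.24 with voom on the recovered reads, 0.0679 with the axis score as a covariate and 0.0810 with the 5 libraries with an axis score above 0 left out. For genes raised in ACLYKO (-0.26) it was -0.46 with only the groups compared in the fit. The correlation of both losses (0.23) was 0.0821 with the axis score as a covariate. None of these medians changed sign.

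Leaving out each library in turn gave 3458 to 5204 for GLUT3 loss, 1778 to 3606 for ACLY loss, 451 to 641 for acetate in WT, 960 to 2342 for acetate in GLUT3KO, 1679 to 2941 for acetate in ACLYKO, 3812 to 5883 for the acetate average, 3317 to 3561 for GLUT3 loss with acetate, 1120 to 1758 for ACLY loss with acetate, 40 to 103 for the GLUT3KO interaction, 93 to 386 for the ACLYKO interaction and 4669 to 7282 for GLUT3KO against ACLYKO. It gave 6 to 8 for GLUT3 loss, 5 to 9 for ACLY loss, 9 to 11 for acetate in WT, 5 to 9 for acetate in GLUT3KO and 8 to 12 for acetate in ACLYKO among the gene lists, 0.10 to 0.44 for GLUT3KO-lowered genes, -0.35 to -0.21 for GLUT3KO-raised genes, 0.42 to 0.83 for ACLYKO-lowered genes and -0.41 to -0.20 for ACLYKO-raised genes, and a correlation of both losses of 0.0981 to 0.403. A group left with 2 libraries, or 1 in the fit without 5, is assumed to vary like the others.

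Of the results for named single genes under these alternatives, 26147 stayed on the side of the threshold reported, with the same direction where they passed. Another 1653 no longer passed, 1222 newly passed and 4 changed direction. A change of direction was counted only where the gene passed in the main fit or in the alternative. Genes that passed in neither are among the 26147 whatever their direction. The 4 were Ncoa2 (0.62 under GLUT3 loss, -0.0349 with the GC and length correction), Vldlr (0.50 and -0.0862 likewise), Ndufb10 (0.24 and -0.0572 in the acetate average, likewise) and Cox4i1 (0.29 and -0.0224, as for Ndufb10). On simulated data with independent noise the test found 78.8% to 92.4% of genes changed by 2 on the log2 scale in the 5 comparisons of a loss or of acetate in 1 genotype. It found 38.8% to 62.7% of those changed by 1 and 0% to 10.4% of those changed by 0.5, so smaller changes were mostly not found there with 3 libraries per group. The rates in the real libraries, which share a main axis of variation, may differ.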

Other observations

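Untreated GLUT3KO and ACLYKO cells differed from each other in several gene groups. Type I interferon genes had 1 of 20 tested members higher and 15 lower, and 16 changed adjusted over the list alone (median log2 change -1.45, camera adjusted p = 3.22e-08, adjusted p = 0.0197 with an estimated correlation) in GLUT3KO against ACLYKO. MYC targets and ribosome biogenesis had 0 of 25 tested members higher and 15 lower, and 17 changed adjusted over the list alone (median log2 change -0.86, camera adjusted p = 1.77e-06, adjusted p = 0.202 with an estimated correlation), and p53 targets had 14 of 20 tested members higher and 2 lower, and 17 changed adjusted over the list alone (median log2 change 0.89, camera adjusted p = 0.00445, adjusted p = 0.229 with an estimated correlation). LXR targets had 5 of 6 tested members higher and 0 lower, and 5 changed adjusted over the list alone (median log2 change 0.88, camera adjusted p = 0.00728, adjusted p = 0.276 with an estimated correlation), and T cell identity genes had 8 of 16 tested members higher and 0 lower, and 8 changed adjusted over the list alone (median log2 change 0.59, camera adjusted p = 0.0355, adjusted p = 0.276 with an estimated correlation).

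Ifnb1, which encodes interferon beta and was looked at after the interferon list was seen, stood at 2.94 ± 0.476 TPM in untreated ACLYKO and at 0.0320 ± 0.0554 TPM in ACLYKO with acetate (log2 changes 1.97 ± 0.10 against WT, limma adjusted p = 1.61e-08, and -1.93 ± 0.10 with acetate, limma adjusted p = 5.54e-08). It was listed at 0 in the untreated WT and GLUT3KO groups. Mir6236 took 0.145% to 5.39% of TPM per library and pseudogenes 8.47% to 13.6%. The genetic background label ends in the number 6 in 12 samples and in 7 to 12 in 1 sample each, and was not used.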
